A study of Dicentrarchus labrax with 3 samples.

How the data were processed

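Messenger RNA was sequenced from DLB-1 cells, a cell line derived from the brain of the European sea bass, that had been mock-infected or infected with NNV (nervous necrosis virus, a betanodavirus of fish) for 12 h or 72 h. Per the labels' protocols, total RNA was column-purified, poly(A) libraries were made with a stranded TruSeq kit from 0.5 µg of RNA, and the libraries were read in paired-end mode at 76 bp per end. There was 1 library in each of the 3 groups. The labels give no time of collection for the mock library and do not say how many cultures each library holds.

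The authors deposited 1 table of estimated counts, with 25352 gene identifiers as rows and the 3 libraries as columns. Each column carries a library code that stands in the description of 1 sample only, and columns were assigned by that code. The submitters' processing notes name CASAVA 1.8, STAR and RSEM, without stating the order, settings or the counting strand. The genome build and the gene annotation are not given in the sources used here. The deposited values are not scaled for depth. Between 9.79% and 12.4% of the values of a library were not whole numbers, which a program that divides reads among similar genes produces. In 4729 genes (18.7%) at least 1 value was not whole, and the share of reads assigned to such a gene is less certain. The 12 h column is written with at most 6 significant digits and the other columns with 2 decimals. All estimated counts were rounded to whole numbers.

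Every identifier starts with dicLab1B, the table pairs none with a gene name, and 0 of the 25352 matched the gene identifiers, locus tags, synonyms or accessions of the RefSeq gene table for the sea bass assembly dlabrax2021. The 24 lists of pathway and cell type genes fixed before the data were examined could therefore not be applied. No feature of the table could be recognised as viral. GC content and gene length were not examined for the same reason.

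Total counts were 54163304 in the mock library, 54121856 at 12 h and 56202086 at 72 h. A count of 0 allows a level of up to 3 counts, or 0.0554, 0.0554 and 0.0534 CPM of those totals in the 3 libraries. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules and nothing measures the spread between cultures.

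With 1 library per group no replicate test was possible, and no p-value is given. Libraries were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3. The log2 ratio of 2 libraries was taken on TMM-scaled CPM (counts per 1000000) with a prior count of 2, which understates the ratio of genes with few counts. A gene was examined in a comparison if the higher of the 2 libraries held at least 50 counts. It was called higher or lower if the ratio was at least 2-fold and the exact (Clopper-Pearson) 95% interval of the ratio of the 2 counts excluded no change. These rules, and the rule that at most 2 identifiers per direction and comparison are named, those with the largest ratios, were fixed before the data were examined. Folds and counting intervals printed for named identifiers are ratios of scaled counts without the prior count, whereas their log2 ratios include it. Where the lower library held 0 counts, the fold was computed against 3 counts in that library and is given as a lower bound, as is its log2 value. This bound leaves out counting error in the other library, so it is not the lower limit of the 95% interval.

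The rule was tested on simulated data, drawn as Poisson counts on the real gene levels and library sizes with 200 genes changed. In each of the 3 comparisons it recovered 100.0% of the genes changed 3-fold and 100.0% of those changed 4-fold. It called 1 unchanged gene in 12 h against mock, 1 in 72 h against mock and 2 in 72 h against 12 h. Changed genes were drawn only from those with at least 50 expected counts before the change. The scaling that generated the counts was reused, so scaling error was not covered. To show what culture-to-culture variation alone could yield, unchanged libraries were also simulated 20 times at each assumed coefficient of variation (CV) between cultures from 0 to 0.5. The variation was drawn from a gamma distribution with the same CV for every gene and every library. No other shape and no unequal CVs were tried. The true variation is not known from these libraries.

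The alternatives were DESeq2 1.42.0 size factors, total counts only, upper-quartile scaling, a prior count of 0.5, no minimum count, a minimum of 200 counts, thinning to the shallowest library, and leaving out the 20 most abundant genes of each library before scaling. Leaving out genes with values that were not whole, other orderings of genes by abundance, and the overlap counted over genes examined in either comparison, were added after the data were seen. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.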

Results

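The transcriptome of DLB-1 cells was profiled after mock infection and after 12 h and 72 h of infection with NNV, the virus that causes nervous necrosis in fish larvae and juveniles. Each condition was represented by 1 library, with totals of 54163304 (mock), 54121856 (12 h) and 56202086 (72 h) counts. Counts were found for 17830 genes in the mock library, 17847 at 12 h and 17246 at 72 h, out of 25352 in the table. At least 50 counts were reached by 12332, 12223 and 11673 genes in the same order. The genes are known here by identifier only, so that no gene, pathway or cell type could be named, and none of the differences has a replicate check.

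The 72 h library was the most concentrated on abundant transcripts. Its 100 most abundant genes held 39.9% of all counts, compared with 25.9% at 12 h and 23.2% in the mock library. The single most abundant gene held 2.11% at 72 h, 1.06% at 12 h and 0.966% in the mock library. The 1000 most abundant genes held 72.1%, 60.7% and 57.5%, respectively. The TMM factors were 1.21 for the mock library, 1.10 at 12 h and 0.76 at 72 h.

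**Figure D1:**
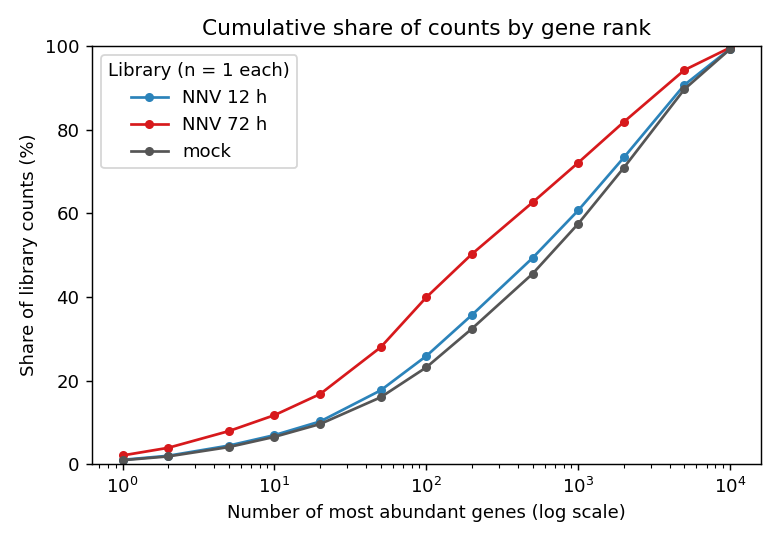
Share of each library's counts (%, vertical axis) held by its most abundant genes, by number of genes (log horizontal axis), with 1 line per library. The 72 h line lies above the other lines, at 39.9% for 100 genes against 25.9% at 12 h and 23.2% in the mock library.

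The first comparison asked how cells infected for 12 h differed from mock-infected cells. Of 12732 genes examined, 1274 were at least 2-fold higher and 1282 at least 2-fold lower at 12 h, together 20.1%. A difference of at least 4-fold was found for 406 higher and 357 lower genes, and of at least 16-fold for 70 higher and 45 lower genes. The median gene differed by 0.45 on the log2 scale in either direction. The gene with the largest ratio, dicLab1B035553, had 31 counts in the mock library and 30122 at 12 h, a ratio of 1069-fold (95% counting interval 753 to 1574). It was followed by dicLab1B016537, with 66 and 31494 counts, a ratio of 525-fold (413 to 679). Among the genes lower at 12 h, dicLab1B038802 had 6201 counts in the mock library and 26 at 12 h, 217-fold lower (148 to 332). The gene dicLab1B040565 had 2244 and 12 counts, 170-fold lower (97.1 to 329).

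The number of genes at 2-fold lay between what unchanged libraries gave at a CV of 0.3 and at a CV of 0.4 between cultures. With a CV of 0.1 they gave medians of 1.0 higher and 2.0 lower genes in this comparison. A CV of 0.2 gave 122.0 and 126.5, with 0.0 genes at least 4-fold apart. A CV of 0.3 gave 726.5 higher and 738.5 lower genes, and a CV of 0.4 gave 1520.5 and 1525.5. In this simulation, with the same CV for every gene and library, a CV between 0.3 and 0.4 was needed to match the 2-fold counts. Uneven variation was not simulated. Time in culture and library preparation were not separated from a response to infection. The large ratios were less easily matched: 763 genes were at least 4-fold apart at 12 h, against 27.5 simulated with a CV of 0.3 and 267.5 with a CV of 0.4, and 865.5 with a CV of 0.5. That CV of 0.5 also gave 2196.5 higher and 2249.5 lower genes at 2-fold, more than observed, so that no assumed CV, the same for every gene, gave both the 2-fold and the 4-fold counts.

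The second comparison set the cells infected for 72 h against the mock-infected cells and gave the largest differences of the 3 comparisons. Of 12701 genes examined, 2295 were at least 2-fold higher and 2868 at least 2-fold lower, together 40.7%. At least 4-fold differences were found for 756 higher and 1069 lower genes, and at least 16-fold differences for 179 higher and 120 lower genes. The median gene differed by 0.80 on the log2 scale. The genes with the largest ratios were dicLab1B035553, with 31 and 50241 counts, 2491-fold higher (1755 to 3667), and dicLab1B026370, with 126 and 122699 counts, 1497-fold higher (1257 to 1797). The gene dicLab1B038802 had 3 counts left at 72 h and was 1345-fold lower, with a wide counting interval of 460.0 to 6523. The gene dicLab1B018333 had 727 counts in the mock library, 81 at 12 h and 0 at 72 h, and was at least 158-fold lower.

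The balance between higher and lower genes at 72 h depended on the scaling. With TMM, 44.5% of the 2-fold genes were higher. With total counts alone, the median of all examined genes shifted by -0.67 on the log2 scale and 1082 genes were higher and 5268 lower. DESeq2 size factors gave 2372 higher and 2792 lower genes, and upper-quartile scaling 2353 and 2808. In simulated unchanged libraries with a CV of 0.5, 2137.5 genes were higher and 2256.5 lower, and 855.0 genes were at least 4-fold apart, against 1825 observed. A CV of 0.2 gave 114.5 higher and 132.0 lower genes, and 0.0 at least 4-fold apart.

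**Figure D2:**
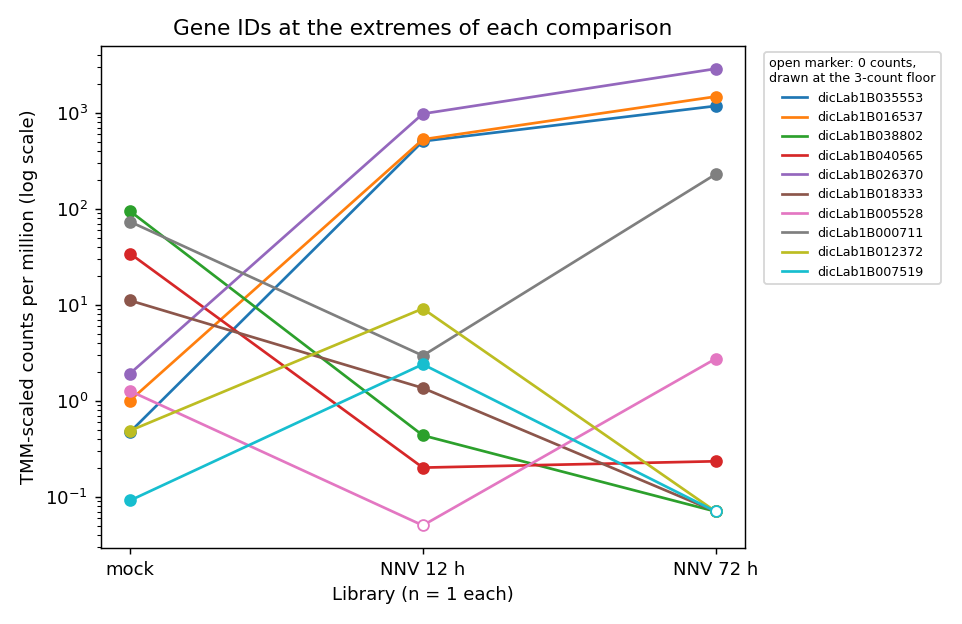
TMM-scaled CPM (log vertical axis) of 10 gene identifiers, the 2 with the largest ratios in each direction of each comparison, in the mock, 12 h and 72 h libraries; each point is 1 library, and an open marker is a count of 0 drawn at the floor of 3 counts. The 3 identifiers that end highest reached 1182, 1482 and 2887 scaled CPM at 72 h, from 0.475, 1.01 and 1.93 in the mock library.

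The spread of gene levels was widest at 72 h, with an SD of log2 levels over 12900 genes of 2.73, compared with 2.50 at 12 h and 2.50 in the mock library. The median 72 h to mock ratio was higher in the most abundant group than in the least abundant under each ordering of genes tried. The size of that rise depended on the ordering. Ordered by their mock level into 5 groups of equal size, the median log2 ratio was -0.31 in the least abundant group and -0.08 in the most abundant. It went from -0.30 to 0.36 when ordered by the 12 h level, from -0.41 to 0.72 by the 72 h level and from -0.46 to 0.38 by the mean of mock and 72 h. Ordering by mock, the denominator of the ratio, favours a fall, and ordering by 72 h a rise. Whether ordering by the 12 h level favours either was not tested. With total counts alone the medians ordered by the 12 h level were -0.95 and -0.31.

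The third comparison set the infected libraries of 72 h and 12 h against each other. No mock library is labelled with either time, so time in culture was not separated from the course of infection. Of 12462 genes examined, 1349 were at least 2-fold higher and 1807 at least 2-fold lower at 72 h, together 25.3%. With total counts alone the split was 522 higher and 3941 lower. At least 4-fold differences were found for 263 higher and 410 lower genes. The gene dicLab1B005528 had 83 counts in the mock library, 0 at 12 h and 117 at 72 h, and was at least 54.5-fold higher at 72 h than at 12 h. The gene dicLab1B000711 had 4813, 176 and 9777 counts, 77.6-fold higher at 72 h than at 12 h (66.8 to 90.6). In the other direction, dicLab1B012372 had 32, 544 and 3 counts, 130-fold lower at 72 h than at 12 h (44.2 to 631). The gene dicLab1B007519 had 6, 143 and 0 counts and was at least 34.1-fold lower. Of the 10 identifiers named, dicLab1B040565, dicLab1B018333, dicLab1B005528 and dicLab1B007519 had whole values in all libraries, and the others had at least 1 value that was not whole, so that reads may be divided with similar genes. In unchanged libraries with a CV of 0.4, this comparison gave 1434.0 higher and 1501.0 lower genes at 2-fold. It gave 270.5 genes at least 4-fold apart, against 673 observed. With a CV of 0.5 it gave 2146.0, 2213.0 and 841.0, and with a CV of 0.2 it gave 120.0, 130.5 and 0.0.

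Genes that differed at 12 h mostly differed in the same direction at 72 h. Of the 1274 genes higher at 12 h than in mock, 830 (65.1%) were also higher at 72 h. Another 143 of them were not examined at 72 h, since they were below 50 counts in both the mock and the 72 h library; without these the share was 73.4% of 1131, but leaving them out favours agreement. Of the 1282 lower at 12 h, 1015 (79.2%) were also lower at 72 h. Independent lists of these sizes (1274 and 2295 higher, 1282 and 2868 lower) among 12900 genes would share 227 and 285 genes. Both comparisons use the same mock library, which could not be split. Unchanged libraries sharing a mock library gave 0 and 0 shared genes with counting error only, 598.5 higher and 450.5 lower shared genes with a CV of 0.4, and 1006.5 and 794.5 with a CV of 0.5. The 1006.5 came from a longer list than the one observed, since a CV of 0.5 gave 2196.5 genes higher at 12 h. The shared control could account for part of the overlap, or for more of it if the mock library varied more than the others, which was not simulated. With total counts alone, 544 higher and 1429 lower genes were shared. In opposite directions, 24 genes were higher at 12 h and lower at 72 h, and 15 were lower at 12 h and higher at 72 h. Independent lists, without the effect of a shared mock library, would share 283 and 228.

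Across the 12900 genes with at least 50 counts in any library, the log2 ratios at 12 h and 72 h were correlated with a Pearson r of 0.74 and a Spearman rho of 0.72. Genes are not independent replicates. Simulated unchanged libraries gave an r of 0.44 with counting error only and 0.50 with a CV of 0.4. The covariance of the log2 ratios was 1.17. Simulated values were 0.0051 with counting error only (a difference of 1.16), 0.37 with a CV of 0.4 and 0.60 with a CV of 0.5. A mock library that varied more than the others was not simulated and could raise both the correlation and the covariance.

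**Figure D3:**
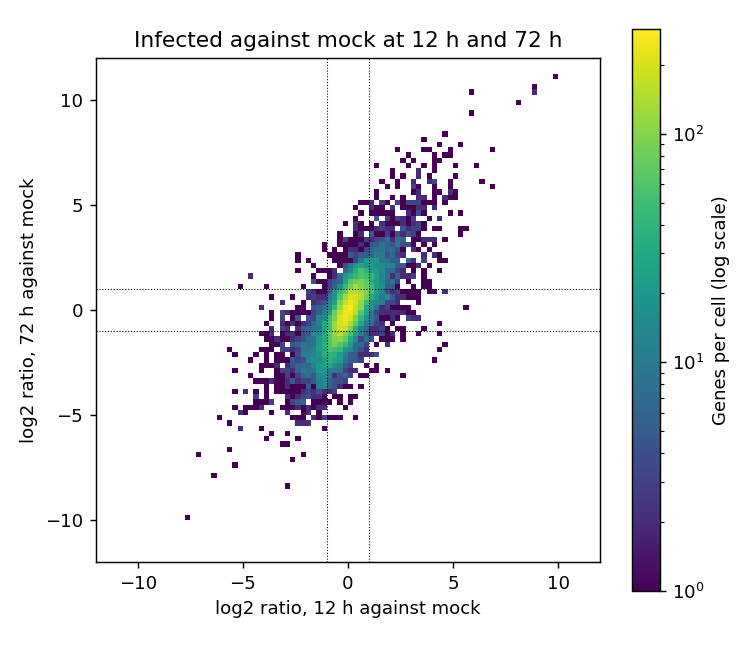
Density of genes by log2 ratio at 12 h against mock (horizontal axis) and 72 h against mock (vertical axis), for 12900 genes; colour gives genes per cell on a log scale and dotted lines mark 2-fold. Most genes beyond the lines of both axes lie in the quadrants of equal direction, with 830 higher and 1015 lower at both times.

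The 2295 genes higher at 72 h were a median of 1.61 above mock on the log2 scale, and had a median of 46.8% of that log2 difference at 12 h (quartiles 25.4% and 71.6%). For the 2868 lower genes the median difference was 1.70 and the share at 12 h was 40.3% (21.8% and 62.1%). At 12 h, 830 of the higher and 1015 of the lower genes were already 2-fold from mock. Because both differences use the mock library, such shares arise without any response: unchanged libraries with a CV of 0.4 gave 58.8% for higher and 41.4% for lower genes. The gap between these simulated shares may come from the assumed gamma shape of the variation. The observed shares were not above the simulated ones, but another shape could change this comparison. Between 12 h and 72 h, 1025 of the higher and 1370 of the lower genes differed 2-fold.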

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

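The 12 h pattern weighed here was noticed in the data, and the bound for its test was written before the tested value was seen.

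Opposite directions against mock at the 2 times were found for 24 genes that were at least 2-fold higher at 12 h and at least 2-fold lower at 72 h, and for 15 genes with the reverse course. With 1 library per time the difference between the times was not tested. Total-count scaling turned these numbers into 36 and 6, and DESeq2 size factors into 21 and 16. Among the named identifiers, dicLab1B000711 had a log2 ratio of -4.62 at 12 h (24.9-fold lower, 21.4 to 29.1) and 1.64 at 72 h (3.12-fold higher, 3.02 to 3.23). The identifier dicLab1B005528 had 0 counts at 12 h, which gives a bound of -4.65 on the log2 scale (at least 25.1-fold lower than mock), and a log2 ratio of 1.09 at 72 h (2.17-fold higher, 1.62 to 2.91). With total counts alone, both identifiers were less than 2-fold higher than mock at 72 h.

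More widely, 153 genes were at least 2-fold lower at 12 h than in both other libraries and 253 were at least 2-fold higher at 12 h than in both. With total counts alone these numbers were 102 and 367, and with DESeq2 size factors 166 and 233. In unchanged libraries with a CV of 0.3, the mock library lay 2-fold below both others for 232.5 genes and above both for 149.5. A CV of 0.2 gave 20.5 and 12.5, and a CV of 0.4 gave 598.5 and 450.5. The same was not counted for the 12 h library. In the data the mock library lay below both others for 830 genes and above both for 1015, and the 72 h library for 1370 and 1025. Division of reads among similar genes is argued against for most of the 406 genes that stood apart at 12 h, as far as values that are not whole reveal it. A whole value does not exclude it, since all shared reads may have gone to a similar gene. Only 21.9% of the 406 genes had a value that was not whole in any library. That share was within the 20.7% to 28.1% of randomly drawn genes of the same abundance. Division of reads stays open for the 89 genes that had such values. Among them were 9 of the 15 genes that were lower and then higher, and 2 of the 24 that were higher and then lower. A transient change at 12 h may underlie the rest. Variation between cultures, or a peculiarity of the single 12 h culture or its library preparation, would look the same. The design holds nothing to separate them.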

How the results depend on the processing

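No count of 2-fold genes changed by more than 1.5 times under DESeq2 size factors, upper-quartile scaling, a prior count of 0.5, thinning, a minimum of 200 counts or leaving out the most abundant genes. Total-count scaling changed 4 of the 6 counts: 72 h against mock gave 1082 higher and 5268 lower genes, and 72 h against 12 h gave 522 higher and 3941 lower. Total counts take no account of the larger share of counts held by abundant genes at 72 h. TMM, DESeq2 and upper-quartile scaling all set the typical gene near no change, so that their agreement is partly built in. These data cannot tell which scaling is right. Without a minimum count, 1936 genes were higher at 12 h than in mock, because more genes were examined. Leaving out genes with values that were not whole, an alternative chosen after seeing the data, gave 1445 genes higher and 2125 lower at 72 h than in mock. Fewer genes were examined, but the higher genes lost more than the lower ones. Of the 2-fold genes 40.5% were then higher, against 44.5% with all genes, so that part of the higher calls rests on genes with divided reads. The correlation of the 2 sets of ratios was 0.76 with a minimum of 200 counts, and the cause was not tested. Of 76 alternative values for the named identifiers, 6 moved, all under total counts, and 0 changed direction. Of the 70 others, 52 stayed within the counting interval of the ratio. The other 18 belong to identifiers with 0 counts in a library, for which the interval has no finite upper limit and was not printed. Their bound was followed instead, and it stayed within the 95% Poisson interval of the count in the other library. The gene list alternatives were not run because the identifiers carry no names. Leaving out replicates was not possible with 1 library per group. Among genes with 50 or more counts the rule recovered simulated 3-fold changes, with the scaling taken as known. In the data, 12900 of the 25352 genes reached 50 counts in any library, and changes in the others were not assessed at that minimum. The missing replicates leave the spread between cultures unknown.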

Other observations

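All tests in this part were chosen after the results were seen.

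The 3 libraries fell into an order. Across 12900 genes the 12 h level lay between mock and 72 h for 56.6%, the 72 h level lay between the others for 20.2% and the mock level for 23.1%. Unchanged simulated libraries gave 33.2% to 34.4% for the 12 h library. With the 12 h library as the reference, the covariance of the log2 ratios of the other libraries was -0.09, whereas simulated libraries with independent variation gave positive values, from 0.0055 with counting error only to 0.60 with a CV of 0.5. With mock or 72 h as the reference it was 1.17 and 1.14. Among genes 2-fold apart between mock and 72 h, 82.7% had a 12 h level in between, but this share is a weak measure, since unchanged libraries gave 59.2% with a CV of 0.5 and 86.0% with a CV of 0.2.

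One explanation for an intermediate 12 h library is a mixture, in which a single proportion of RNA of the 72 h type, from a fixed share of fully responding cells or from carry-over, was added to RNA of the mock type. The 12 h level of genes at least 16-fold higher at 72 h, as a percent of 72 h, and that of genes at least 16-fold lower, as a percent of mock, would then add up to about 100%. The medians were 20.3% over 179 higher genes and 19.1% over 120 lower genes, where the higher genes predict 79.7% for the lower. Their sum was 39.4% (46.8% with total counts), and even the 75th percentiles added up to 68.5%, which argues against a single proportion. Infection was not tested as the cause, and time in culture remains open beside it, because the labels give no collection time for the mock library.

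The concentration of counts on abundant genes at 72 h was not due to a few genes alone. After the 20 most abundant genes of each library (37 in all) were left out, the 100 next genes still held 13.6 percentage points more of the counts at 72 h than in mock, against 16.7 points with all genes. A constant background of stray reads in the mock library would alter scarce genes and leave abundant ones as they are. It was argued against by the 1000 most abundant genes of each library. Of their counts the first 100 held 55.4% at 72 h and 40.3% in mock, a gap of 15.1 percentage points. Counts of 0 do not decide it: 7522 identifiers had 0 counts in the mock library, 7505 at 12 h and 8106 at 72 h. Infection, time in culture and differences in RNA quality or in amplification between single libraries were not tested as causes and could look alike.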
